A study of Methylotenera mobilis and Methylobacter tundripaludum
Methylotenera mobilis and Methylobacter tundripaludum with 10 samples.

How the data were processed

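RNA was sequenced from 10 bacterial cultures as single reads of 50 bp on an Illumina HiSeq instrument, per the labels. The 10 libraries form 5 groups of 2, and their titles give each library its culture and replicate number. The cultures were Methylobacter tundripaludum 31/32 alone, Methylotenera mobilis strain 13 alone, M. mobilis strain JLW8 alone, and M. tundripaludum together with either M. mobilis strain. Per the labels, cells were harvested at an optical density of about 0.5 after growth at 18 °C with about 15 µM dissolved oxygen at the start of each gas exchange. The labels name 30 µM lanthanum chloride for the pre-growth cultures and speak of RNA from cultures with and without lanthanum. They do not say which libraries had it.

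The deposited files are 3 tables, 1 for the genes of each strain, and a co-culture library has a column in 2 of them. The deposited values are a signal per gene, namely normalized read counts that are not whole numbers. Per the submitters' processing notes, the tools were BWA 0.7.12-r1044, SAMtools 1.2-232, HTSeq, DESeq2 1.2.10, DESeq and R 3.2.4, with no role given for each. The genome builds and annotations used by the authors are not given in the sources used here, so genes are named by the locus tags and product texts in the files, with no coordinates. The files carry no gene symbols and no ribosomal or transfer RNA genes.

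In each of the 14 columns, every deposited value was a whole multiple of 1 step, within 0.01 of a read for 100% of values. The steps equalled size factors of the median-of-ratios kind with a relative difference of at most 1.52e-10. Dividing by the step gave the read totals that are printed as depth. An independent check of steps at low values could be made for too few genes in most columns, so these reads served only for depth, shares, thinning and alternative fits, and the main test used the deposited values. Each table was tested on its own.

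The design fixed before the data were examined assumed raw counts and a count-based test. Because the files hold normalized values, the main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a pseudocount of 1, a mean-variance trend and robust moderation of the variances. Genes entered with a value of at least 10 in at least 2 libraries. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and errors of log2 fold changes are standard errors. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with 0.05 as the threshold. The 3 groups of M. tundripaludum libraries shared 1 fit, and each M. mobilis strain had its own. With 2 libraries a group, limma borrows spread across genes. The median prior degrees of freedom were 6.02 for M. tundripaludum, 3.94 for M. mobilis 13 and 406 for M. mobilis JLW8, so p-values in the JLW8 fit rest almost wholly on the fitted trend. For JLW8, the adjusted p of a second limma fit (voom on the recovered reads), chosen after seeing the data, is therefore printed beside the JLW8 genes that the rule below names in the report. The limma trend gives a gene 1 spread over all libraries, although M. mobilis genes had far fewer reads in co-culture than in pure culture. Voom weights values by their reads, and it called 1791 strain 13 genes against 1764 and 56 JLW8 genes against 614. Thinning all libraries to the smallest total gave 1616 for strain 13 and 618 for JLW8.

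Before the data were examined, 26 gene lists were written as patterns on product texts. Each list with at least 3 tested genes was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The latter setting tests on the 2 or 3 residual degrees of freedom of a fit. It can therefore hardly reach the threshold, whatever the correlation is. The estimated correlations were near or below the preset in some lists, with 0.023 for the chaperone list of M. tundripaludum. In others they were far above it, with 0.479 for its ribosomal protein list, 0.71 for that of JLW8 and 0.63 for the ATP synthase list of strain 13. Where such estimates hold, camera p-values at the preset are too small. Patterns also catch neighbours in name: the chaperone list holds nitrate reductase and iron-sulfur assembly chaperones, the metal list holds a cytochrome oxidase subunit, and the list of oxygen carriers and fermentation holds dehydrogenase subunits. Named genes followed a rule with 3 parts: the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 log2 CPM, both libraries of one group above both of the other and a usable product text; the 2 members with the smallest adjusted p from each list that was called or had at least 3 changed members; and, whatever the result, the large subunits of methanol dehydrogenases, methane monooxygenase, hexulose-6-phosphate synthase and the main nitrate, nitrite and nitric oxide reductases. Other genes are named as chosen after their values were seen.

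The labels call the libraries duplicates, with titles ending in BR1 or BR2, and do not state that they came from separate cultures. P-values therefore measure the spread between these libraries, which may be technical, and in the JLW8 fit mostly the fitted trend. Replicates differed by more than sampling noise in all 7 pairs of columns, with a chi-square per degree of freedom from 9.38 to 827, the highest in the JLW8 pure cultures. Depth was 23420623 to 29330789 reads per library on M. tundripaludum genes and 24890583 to 28586972 in the M. mobilis pure cultures. In co-culture it was 1513904 to 3476499 reads on M. mobilis genes. Intervals on read shares are exact 95% binomial intervals and cover counting error only. In simulated data with the real means and depths, 200 genes were changed and genes varied independently. The spreads were those that limma had fitted, so the figures take that fit as true and do not test it. This bears most on strain JLW8, whose fitted spreads came almost wholly from the trend. Limma recovered 83% of 2-fold and 98% of 4-fold changes for M. tundripaludum with strain 13, and 93% and 99% with strain JLW8, among 4418 genes. It recovered 90% and 97% between the partners, 97% and 100% for strain 13 among 2579 genes, and 57% and 94% for strain JLW8 among 2338 genes. Of the genes called in these simulations, 21 of 202, 17 of 208, 17 of 204, 16 of 213 and 6 of 157 were unchanged, in the same order, which is above the 5% aimed at in all but the last-named comparison.

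Alternatives covered the scaling, the low-value filter, a replicate block, each library left out, a 2-fold minimum, thinning to the smallest total and a fit of only the groups compared. Added after seeing the data were scaling by total reads, pseudocounts of 0.1 and 10, fits without robust moderation, voom, a split of the pure-culture libraries for the correlation of both partner responses, and for JLW8 a higher minimum mean. The planned edgeR and DESeq2 fits were not run here, since the files hold no raw counts.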

Results

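The libraries came from methylotrophs of Lake Washington sediment, bacteria that grow on carbon compounds with no carbon-carbon bond. M. tundripaludum is a methanotroph, which oxidises methane by way of methanol. The M. mobilis strains are methylotrophs that do not use methane. Pure cultures of M. mobilis were fed 0.1% methanol, and all cultures with M. tundripaludum were fed 25% methane. The design asks how each organism's transcripts differ between growth alone and growth with a partner. In the M. mobilis comparisons the partner and the supplied carbon source changed together, so the values cannot separate them. The labels do not say which libraries had lanthanum, so in every comparison a difference in lanthanum between the groups is not excluded.

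In the pure cultures, M. tundripaludum libraries held 29330789 and 29018330 counted reads, strain 13 libraries 28206537 and 24890583, and strain JLW8 libraries 28586972 and 28380499. In co-culture with strain 13, M. tundripaludum genes had 25836585 and 28905094 reads and strain 13 genes 3374556 and 1513904. In co-culture with strain JLW8, M. tundripaludum genes had 23420623 and 25650104 reads and JLW8 genes 2199932 and 3476499. M. mobilis 13 thus gave 8.27% ± 4.65 (SD, n = 2) of the counted reads in its mixture, with 11.6% (exact 95% binomial interval 11.5% to 11.6%) in replicate 1 and 4.98% (4.97% to 4.98%) in replicate 2. M. mobilis JLW8 gave 10.3% ± 2.37 (SD, n = 2), with 8.59% (8.58% to 8.60%) in replicate 1 and 11.9% (11.9% to 11.9%) in replicate 2. The cells were mixed at equal starting densities, per the labels.

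With M. mobilis 13 as partner, M. tundripaludum raised genes of protein folding and turnover, siderophore synthesis and metal efflux. The chaperone ClpB (T449DRAFT_2064), which resolves protein aggregates, rose from 9452 ± 1563 to 64880 ± 32910 normalized counts (mean ± SD, n = 2 per group), a log2 change of 2.69 ± 0.38 (limma adjusted p = 0.0362). The chaperone DnaK (T449DRAFT_3030) rose by 2.15 ± 0.37 and the chaperonin GroL (T449DRAFT_0925) by 2.12 ± 0.35. A periplasmic protease of the Do family (T449DRAFT_2150) rose by 1.98 ± 0.33 and the protease La (T449DRAFT_3295) by 1.43 ± 0.23. In each of these 5 genes co-culture replicate 1 was higher than replicate 2, with 88155 and 41610 counts for ClpB, and the share of strain 13 reads was also higher in replicate 1. Of 50 measured members of the chaperone list, 5 rose, none fell and 45 did not pass, and 17 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.52e-05). With voom 10 members rose, and under scaling by total reads 2 did. The list had adjusted p = 0.487 with an estimated correlation. The 5 members were ClpB, DnaK, GroL, the protease La and the subunit ClpA (T449DRAFT_0335, log2 1.02, adjusted p = 0.0337), which was named after its values were seen. The calls of ClpB, DnaK, GroL and both proteases did not hold without pure-culture replicate 1, without pure-culture replicate 2 or under scaling by total reads, where ClpB had adjusted p = 0.219, 0.165 and 0.0951 with log2 changes of 2.52, 2.86 and 2.75. ClpA held its call under scaling by total reads (adjusted p = 0.0182), and lost it without pure-culture replicate 1 or 2 or co-culture replicate 1 (adjusted p = 0.273, 0.165 and 0.139). In a fit of these 2 groups alone ClpB had adjusted p = 0.127.

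**Figure D1:**
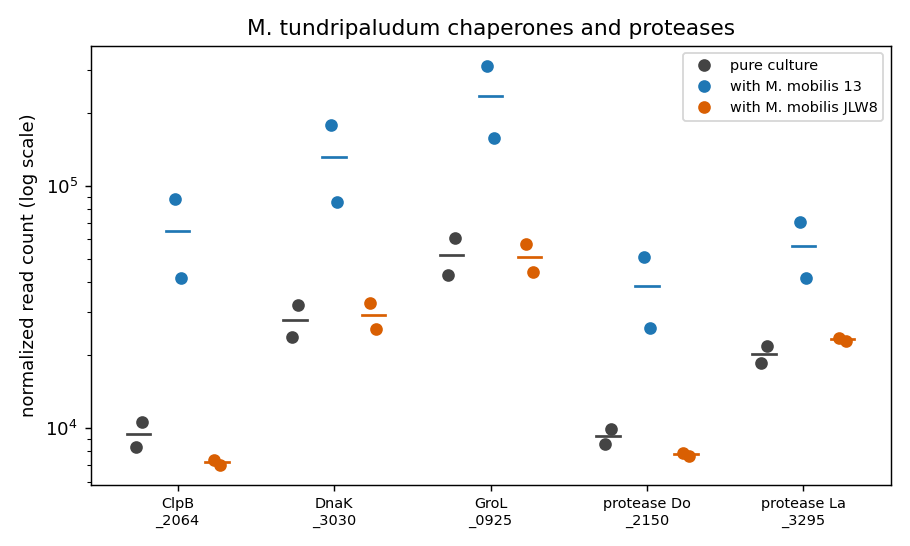
Normalized read counts (log axis) of 5 chaperone and protease genes of M. tundripaludum in its pure culture and in both co-cultures, with a point per library and a line at the mean of 2 libraries. ClpB had 88155 and 41610 counts with M. mobilis 13 against 8346 and 10557 in pure culture.

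Iron and metal genes moved as well. A siderophore synthetase (T449DRAFT_3946) rose from 175.5 ± 2.79 to 1434 ± 292.7 counts, a log2 change of 3.01 ± 0.16 (limma adjusted p = 3.34e-05), and the siderophore receptor T449DRAFT_3950 rose by 1.47 ± 0.19, a call lost without either pure-culture library (adjusted p = 0.1 without replicate 1 and 0.0989 without replicate 2). In the other direction, the receptor for the siderophore ferrienterochelin (T449DRAFT_3237) fell by 1.61 ± 0.10 on the log2 scale (adjusted p = 4.58e-05). In the list of TonB receptors, siderophores and iron transport, 2 of 18 rose, also when adjusted over the list alone (camera adjusted p = 0.042, and adjusted p = 0.619 with an estimated correlation). These 2 were T449DRAFT_3946 and T449DRAFT_3950, which lie in 1 run of neighbouring genes. The pattern of the list did not catch the falling receptor T449DRAFT_3237. In the metal efflux and copper list 8 of 33 rose and 2 fell, and 9 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.000187, and adjusted p = 0.487 with an estimated correlation). Its members included the heavy metal efflux pumps T449DRAFT_0845, which rose by 1.56 ± 0.13, and T449DRAFT_1153, which rose by 1.01 ± 0.10. A predicted multicopper oxidase (T449DRAFT_0477) fell by 0.91 ± 0.17 on the log2 scale, a call lost without pure-culture replicate 1 or 2 or co-culture replicate 1 (adjusted p = 0.199, 0.195 and 0.076).

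Few genes of nitrogen and oxygen metabolism passed: 0 of 13 nitrogen assimilation genes, with 1 lower adjusted over the list alone, and 0 of 5 denitrification genes, also adjusted over the list alone. Of 63 oxygen carrier and fermentation genes 1 rose and 2 fell, with 2 and 8 adjusted over the list alone. Outside the nitrogen lists, the hydroxylamine reductase gene T449DRAFT_2451 rose from 830.2 ± 19.8 to 3579 ± 92.6 counts (log2 2.11 ± 0.13, adjusted p = 8.12e-05), and truncated hemoglobin (T449DRAFT_2569), an oxygen-binding protein, rose by 2.18 ± 0.15. The gene for an assimilatory-type nitrite reductase using NAD(P)H (T449DRAFT_1702), which the patterns of the nitrogen lists did not catch, fell by 0.63 ± 0.12 on the log2 scale (adjusted p = 0.0181). That call was lost without pure-culture replicate 1 or 2 or co-culture replicate 2 (adjusted p = 0.0539, 0.175 and 0.061). Among terminal oxidases 1 of 18 rose and 2 fell, with 2 and 2 adjusted over the list alone. A subunit of a cbb3-type oxidase (T449DRAFT_0836) rose by 1.21 ± 0.09 and subunit II of cytochrome d oxidase (T449DRAFT_4417) fell by 0.64 ± 0.11 on the log2 scale, a call lost without pure-culture replicate 1 or 2 or co-culture replicate 1 (adjusted p = 0.154, 0.124 and 0.0509). Beside it, the small cyd operon protein YbgT (T449DRAFT_4416) fell by 0.78 ± 0.09. In the pilus and secretion list 7 of 50 rose, also when adjusted over the list alone, among them the Flp pilus genes TadB (T449DRAFT_0647, log2 0.80 ± 0.10) and CpaF (T449DRAFT_0646, 0.78 ± 0.10). Camera did not call that list (adjusted p = 0.121).

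Of 14 polysaccharide and storage genes 2 rose and 1 fell, with 2 and 2 adjusted over the list alone, and the capsular exopolysaccharide gene T449DRAFT_3274 rose by 0.90 ± 0.12 (adjusted p = 0.0578 without pure-culture replicate 2). The list of mobile elements had 3 of 121 members lower, 0 when adjusted over the list alone (camera adjusted p = 0.0215, and adjusted p = 0.517 with an estimated correlation), among them a Mu-like prophage gene (T449DRAFT_3816) that fell by 1.17 ± 0.25 on the log2 scale. No member of the 17 ATP synthase genes passed either way, although camera called the list lower at a median log2 change of -0.17 (adjusted p = 0.0285, and adjusted p = 0.487 with an estimated correlation). In the list of conserved genes 3 of 18 rose and 5 rose when adjusted over the list alone (camera adjusted p = 0.00328, and adjusted p = 0.487 with an estimated correlation), among them GroL and the elongation factor GreA (T449DRAFT_0908, log2 0.41 ± 0.08). Further falls past the threshold included a beta-lactamase-fold enzyme (T449DRAFT_0613, log2 -1.20 ± 0.11), the neighbouring diguanylate cyclase (T449DRAFT_0614, -0.93 ± 0.10) and a cAMP-binding protein (T449DRAFT_3783, -0.81 ± 0.14). Without pure-culture replicate 1 the calls of T449DRAFT_3816, T449DRAFT_0908 and T449DRAFT_3783 were lost (adjusted p = 0.219, 0.246 and 0.155), and so they were without co-culture replicate 1 (adjusted p = 0.165, 0.129 and 0.079), while without pure-culture replicate 2 those of T449DRAFT_3816 and T449DRAFT_0908 were lost (adjusted p = 0.218 and 0.152).

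The genes of carbon entry did not pass. Subunit A of methane monooxygenase (T449DRAFT_2847) had 1899000 ± 455900 counts with strain 13 and 2509000 ± 274000 alone (log2 -0.42 ± 0.31, adjusted p = 0.489). The large subunit of the calcium-type methanol dehydrogenase (T449DRAFT_4155), the enzyme that oxidises methanol, had 213900 ± 160100 against 41090 ± 17570 counts (log2 2.21 ± 0.68, adjusted p = 0.17), and passed without co-culture replicate 2 (log2 3.06, adjusted p = 0.00296). The methanol dehydrogenase list holds T449DRAFT_4155 with its neighbours T449DRAFT_4152 and T449DRAFT_4154. The list had a median log2 change of 2.30 with 0 of 4 members past the threshold, also when adjusted over the list alone, and camera did not call it (adjusted p = 0.0603). It did so under scaling by total reads (adjusted p = 0.0212) and without co-culture replicate 1 or 2 or pure-culture replicate 2 (adjusted p = 0.0225, 0.0216 and 0.0344), while the list had adjusted p = 0.517 with an estimated correlation. Hexulose-6-phosphate synthase (T449DRAFT_1929), which fixes formaldehyde, had a log2 change of -0.24 ± 0.19 (adjusted p = 0.529), and the alpha subunit of respiratory nitrate reductase (T449DRAFT_3186) one of 0.07 ± 0.10 (adjusted p = 0.721). Over all 4418 genes tested, limma called 190 changed, 110 higher and 80 lower, and 57 changed at least 2-fold. Leaving out replicate 1 or 2 of the pure culture gave 48 and 54 genes, and leaving out co-culture replicate 2 gave 317. Scaling by total reads gave 123 higher and 49 lower, a split of 71.5% higher in place of 57.9%.

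With M. mobilis JLW8 as partner, hydroxylamine reductase (T449DRAFT_2451) rose further, from 830.2 ± 19.8 to 9070 ± 1886 counts (log2 3.43 ± 0.13, limma adjusted p = 3.22e-06). In a run of efflux genes, an outer membrane efflux lipoprotein (T449DRAFT_2563) fell from 61100 ± 2611 to 12540 ± 1122 counts (log2 -2.29 ± 0.14, adjusted p = 2.51e-05). Its neighbours fell as well: a multidrug efflux pump (T449DRAFT_2562, -2.27 ± 0.13), a drug resistance transporter (T449DRAFT_2564, -2.16 ± 0.12) and a nucleoside phosphorylase (T449DRAFT_2561, -1.64 ± 0.08). The copper-resistance gene of the CopA family (T449DRAFT_0833) rose by 1.06 ± 0.12 (adjusted p = 0.00537) and the nearby metal-binding protein T449DRAFT_0835 by 0.87 ± 0.10. The siderophore synthetase T449DRAFT_3946 rose by 1.25 ± 0.16 and squalene-hopene cyclase (T449DRAFT_0264), which makes hopanoid membrane lipids, by 0.78 ± 0.14. Chain M of NADH-quinone oxidoreductase (T449DRAFT_2522) fell by 0.80 ± 0.13 on the log2 scale and was the single member past the threshold among 29 complex I genes. The calls of T449DRAFT_0833, T449DRAFT_0835, T449DRAFT_3946 and T449DRAFT_2522 did not hold without either pure-culture library, with adjusted p = 0.153, 0.153, 0.174 and 0.441 without replicate 1 and 0.102, 0.102, 0.104 and 0.126 without replicate 2. That of T449DRAFT_0264 did not hold without any of the 4 libraries taken singly (adjusted p from 0.0711 to 0.283).

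The methanol dehydrogenase genes did not pass the test over all genes in the fit of all groups, and passed in some other fits. The calcium-type large subunit (T449DRAFT_4155) had 1174500 and 760820 counts with JLW8 and 28666 and 53513 alone, a log2 difference of 4.59 ± 0.68 (adjusted p = 0.081). The PQQ-dependent dehydrogenase T449DRAFT_3928, of the family that includes lanthanide-dependent methanol dehydrogenases, had 154920 and 184970 counts with JLW8 and 428200 and 473390 alone (log2 -1.41 ± 0.31, adjusted p = 0.078). In a fit of these 2 groups alone T449DRAFT_4155 and T449DRAFT_3928 passed over all genes (adjusted p = 0.000429 and 0.022), and T449DRAFT_4155 also passed without robust moderation (adjusted p = 0.0155). In the list of 4 methanol dehydrogenase genes, 3 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000255, and adjusted p = 0.548 with an estimated correlation). These 3 lie in 1 run of neighbouring genes (T449DRAFT_4152, T449DRAFT_4154 and T449DRAFT_4155, log2 5.05, 4.95 and 4.59). T449DRAFT_3928 is not in the list. Within a library, the ratio of the calcium-type gene to T449DRAFT_3928 was 0.0669 and 0.113 in pure culture, 1.52 and 0.243 with strain 13, and 7.58 and 4.11 with JLW8. Subunits C, A and B of methane monooxygenase (T449DRAFT_2846 to T449DRAFT_2848) had log2 changes of -0.03 ± 0.30, 0.08 ± 0.31 and 0.12 ± 0.33, and none passed. The respiratory nitrate reductase gene T449DRAFT_3186 (0.21 ± 0.10), the nitrite reductase T449DRAFT_1702 (-0.27 ± 0.12) and hexulose-6-phosphate synthase (T449DRAFT_1929, -0.15 ± 0.19) did not pass either.

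**Figure D2:**
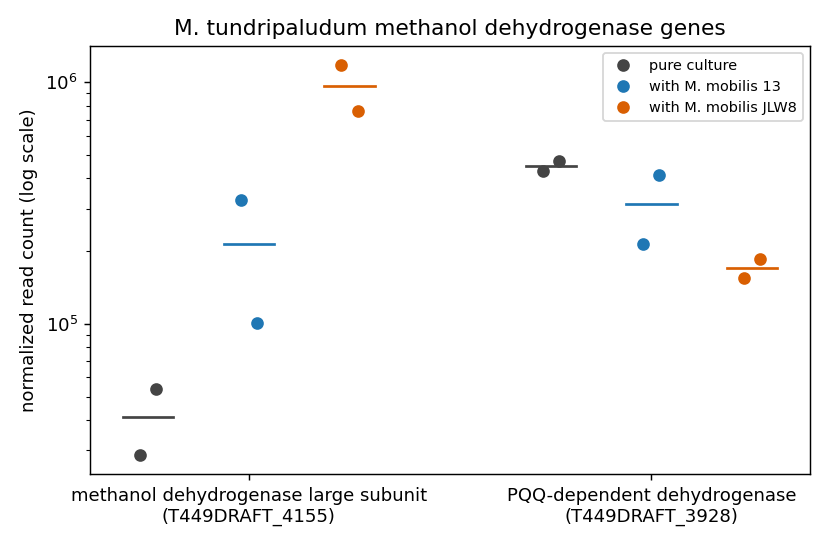
Normalized read counts (log axis) of the calcium-type methanol dehydrogenase large subunit and of the PQQ-dependent dehydrogenase of M. tundripaludum, with a point per library and a line at the mean of 2 libraries per group. The first gene had 28666 and 53513 counts in pure culture and 1174500 and 760820 with M. mobilis JLW8.

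Several lists moved by small steps with JLW8. None of 58 ribosomal protein genes passed on its own, 0 also when adjusted over the list alone, and the list had a median log2 change of 0.29 (camera adjusted p = 1.08e-11, and adjusted p = 0.548 with an estimated correlation of 0.479). Likewise none of 80 flagellar and chemotaxis genes passed, with 0 adjusted over the list alone and a median of 0.12 (camera adjusted p = 0.000255, and adjusted p = 0.548 with an estimated correlation). Camera called the complex I list lower, with 1 member lower over all genes and 7 adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.548 with an estimated correlation). It called the iron transport list higher, with 1 of 18 higher and 2 adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.548 with an estimated correlation). It called the denitrification list higher with 0 of 5 members past the threshold, 0 also adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.548 with an estimated correlation). The pilus and secretion list was called lower with 0 of 50, or 2 higher and 6 lower adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.559 with an estimated correlation). The oxidative stress list was called lower with 1 of 29, also adjusted over the list alone (adjusted p = 0.0425, and adjusted p = 0.548 with an estimated correlation). In the metal efflux and copper list 3 of 33 rose, with 7 higher and 3 lower adjusted over the list alone. Limma called 48 genes, 20 higher and 28 lower, and 11 changed at least 2-fold. Leaving out either pure-culture library gave 7 genes and leaving out co-culture replicate 2 gave 295, while leaving out co-culture replicate 1 gave 30. Scaling by total reads gave 16 higher and 54 lower, a split of 22.9% higher in place of 41.7%, and moved the median log2 change of all genes to -0.11. Under it the complex I list had 4 members lower, and the medians of the ribosomal and flagellar lists were 0.18 and 0.01.

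Set against each other, the co-cultures differed in stress genes, efflux and motility genes of M. tundripaludum. ClpB (T449DRAFT_2064) had 7200 ± 211.5 counts with JLW8 and 64880 ± 32910 with strain 13 (n = 2 each, log2 -3.07 ± 0.38, limma adjusted p = 0.0145). A small heat shock protein (T449DRAFT_2409) was lower with JLW8 by a log2 difference of -2.59 ± 0.38, the co-chaperonin GroES (T449DRAFT_0926) by -2.37 ± 0.39, a chaperone-type protease (T449DRAFT_4567) by -2.43 ± 0.43 and GroL (T449DRAFT_0925) by -2.14 ± 0.35. In the chaperone list 19 of 50 were lower and 0 higher, with 24 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.06e-06, and adjusted p = 0.486 with an estimated correlation). Of 29 oxidative stress genes 9 were lower and 2 higher, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.595 with an estimated correlation). The oxidative stress genes included superoxide dismutase (T449DRAFT_1764, -1.04 ± 0.17) and a monothiol glutaredoxin (T449DRAFT_4368, -1.18 ± 0.21). Except for superoxide dismutase, no call of a gene named here held without JLW8 replicate 1 or without JLW8 replicate 2: ClpB had adjusted p = 0.162 and 0.102, T449DRAFT_2409 0.207 and 0.109, T449DRAFT_0926 0.229 and 0.16, T449DRAFT_4567 0.257 and 0.165, GroL 0.101 and 0.0801 and T449DRAFT_4368 0.217 and 0.143. In a fit of these groups alone T449DRAFT_2409, T449DRAFT_0926 and T449DRAFT_4567 lost theirs (adjusted p = 0.0598, 0.0547 and 0.0758), and under scaling by total reads T449DRAFT_0926, T449DRAFT_4567 and GroL did (adjusted p = 0.0539, 0.0657 and 0.0531).

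The efflux genes T449DRAFT_2562 and T449DRAFT_2563 were lower with JLW8 than with strain 13 by -2.33 ± 0.13 and -2.32 ± 0.14 (adjusted p = 1.64e-05 and 1.91e-05). Truncated hemoglobin (T449DRAFT_2569) was lower by -1.45 ± 0.15, the heavy metal pump T449DRAFT_2503 by -1.04 ± 0.09 and the Flp pilus gene CpaF (T449DRAFT_0646) by -1.14 ± 0.10. In the metal efflux and copper list 10 of 33 were lower and 1 higher, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.595 with an estimated correlation). In the pilus and secretion list 11 of 50 were lower and 1 higher, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.0069, and adjusted p = 0.595 with an estimated correlation). Of 14 polysaccharide genes 3 were lower, also adjusted over the list alone, among them the capsular gene T449DRAFT_3274 (-1.30 ± 0.12).

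Higher with JLW8 were the ferrienterochelin receptor (T449DRAFT_3237, 1.74 ± 0.10, adjusted p = 1.64e-05), hydroxylamine reductase (T449DRAFT_2451, 1.33 ± 0.13), a methyl-accepting chemotaxis protein (T449DRAFT_4400, 1.52 ± 0.24) and a hemerythrin-like protein (T449DRAFT_3653, 2.08 ± 0.40). The call of T449DRAFT_3653 was lost without JLW8 replicate 1 or 2 or strain 13 replicate 1 (adjusted p = 0.119, 0.135 and 0.0882), under scaling by total reads (adjusted p = 0.102) and in a fit of these groups alone (adjusted p = 0.0767). In the flagellar and chemotaxis list 17 of 80 were higher and 3 lower, with 22 and 5 adjusted over the list alone (camera adjusted p = 0.007, and adjusted p = 0.595 with an estimated correlation). Its median log2 difference was 0.08 and turned to -0.09 when libraries were scaled by total reads, with 7 higher and 6 lower. Of 58 ribosomal protein genes 4 were higher, 0 adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.616 with an estimated correlation), and under scaling by total reads 1 was higher and 2 lower, with the median going from 0.23 to 0.05. The calcium-type methanol dehydrogenase gene T449DRAFT_4155 had a log2 difference of 2.38 ± 0.68 without passing (adjusted p = 0.104), and passed without robust moderation (adjusted p = 0.0338) and without strain 13 replicate 1 (log2 3.23, adjusted p = 0.00331). Its list of 4 had 0 members past the threshold, also adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.595 with an estimated correlation). That list also holds its neighbours T449DRAFT_4152 and T449DRAFT_4154, and not T449DRAFT_3928. Limma called 513 genes, 201 higher with JLW8 and 312 lower, and 106 differed at least 2-fold. A fit of these groups alone gave 301 genes, and leaving out single libraries gave 223 without JLW8 replicate 1 and 281 without strain 13 replicate 1. Scaling by total reads gave 13.6% higher in place of 39.2%, with a median log2 difference of all genes of -0.16.

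The responses to the partners shared 17 genes, 14 higher and 3 lower with both, while 7 genes moved in opposite directions. Most of the shared rises lay in a run of genes from T449DRAFT_0826 to T449DRAFT_0836. The run holds the copper-resistance genes T449DRAFT_0832 and T449DRAFT_0833 and the oxidase subunit T449DRAFT_0836. Other shared rises included hydroxylamine reductase (T449DRAFT_2451) with its neighbour T449DRAFT_2450, and the nearby genes T449DRAFT_3946 and T449DRAFT_3948. With JLW8, the calls of T449DRAFT_0832, T449DRAFT_0833 and T449DRAFT_0836 were lost without pure-culture replicate 1 (adjusted p = 0.162, 0.153 and 0.153) or replicate 2 (adjusted p = 0.104, 0.102 and 0.121). Lists of these sizes would share 0.498 higher and 0.507 lower genes if genes were independent, which neighbours that move together are not. Both comparisons used the same pure-culture libraries. In 50 simulations of unchanged groups all libraries were drawn anew, with independent genes, and both comparisons shared the drawn pure cultures. These gave 0.22 shared genes on average and at most 2. The covariance of the log2 changes over genes was 0.0623 against 0.014 in the simulations, a difference of 0.0482. The correlation was 0.412, below the 0.503 of the simulations. With 1 pure-culture library for each comparison, so that none was shared, the correlation was 0.355 or 0.281 and the covariance 0.055 or 0.0467, depending on which library went to which comparison. A test of shared calls on such a split was not made, as each part would hold a single pure-culture library, so part of the excess of shared genes may come from the shared controls. Leaving out either pure-culture library gave 2 shared genes.

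M. mobilis 13 changed most of its transcripts between methanol-fed pure culture and the methane-fed mixture. The lanthanide-dependent methanol dehydrogenase XoxF (A391DRAFT_0600) rose from 3422 ± 95.2 to 950200 ± 86830 normalized counts (mean ± SD, n = 2 per group), a log2 change of 8.11 ± 0.11 (limma adjusted p = 1.68e-07). It took 0.043% and 0.044% of strain 13 reads in pure culture and 13.1% and 11.9% in the mixture. A different dehydrogenase of the same family (A391DRAFT_0895) fell by 4.41 ± 0.25 on the log2 scale, and the less abundant family members A391DRAFT_2044 and A391DRAFT_2073 had log2 changes of -0.66 ± 0.15 and -1.03 ± 0.37. The calls of both were lost without pure-culture replicate 2 (adjusted p = 0.127 and 0.227), and that of A391DRAFT_2073 also without either co-culture library, under scaling by total reads and with voom (adjusted p = 0.196 with voom). Of the 4 genes in the methanol dehydrogenase list 2 rose and 0 fell, with 1 and 0 adjusted over the list alone. Camera did not call the list (adjusted p = 0.492). Its pattern did not catch the falling genes A391DRAFT_0895, A391DRAFT_2044 and A391DRAFT_2073. In the list for the cofactor PQQ 13 of 18 fell and 3 rose, with 14 and 3 adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.474 with an estimated correlation). Among them the precursor peptide genes A391DRAFT_0458 and A391DRAFT_0203 fell, with log2 changes of -2.67 ± 0.22 and -2.95 ± 0.27.

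Genes of iron uptake rose in a block in strain 13. A hemin uptake protein (A391DRAFT_0464) rose from 19.6 ± 2.44 to 2944 ± 610.7 counts (log2 7.15 ± 0.19, adjusted p = 1.27e-06), its neighbour of the TonB family (A391DRAFT_0465) by 6.55 ± 0.17, and the biopolymer transport genes A391DRAFT_0467 and A391DRAFT_0466 by 6.18 ± 0.12 and 6.15 ± 0.13. The siderophore receptors A391DRAFT_0468 and A391DRAFT_1157 rose by 5.81 ± 0.10 and 5.27 ± 0.09. In the iron transport list 8 of 11 rose and 3 fell, also when adjusted over the list alone, and camera did not call it (adjusted p = 0.0587).

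Respiration and growth genes of strain 13 rose together. All 9 denitrification and nitrate respiration genes rose, also when adjusted over the list alone (camera adjusted p = 0.000108, and adjusted p = 0.375 with an estimated correlation). The alpha subunit of respiratory nitrate reductase (A391DRAFT_1597) went from 1338 ± 132.7 to 54270 ± 8343 counts (log2 5.34 ± 0.14), the beta subunit (A391DRAFT_1596) rose by 4.64 ± 0.13, the nitrate/nitrite transporter A391DRAFT_1599 by 6.13 ± 0.11 and nitric oxide reductase (A391DRAFT_1676) by 2.18 ± 0.10. Of 19 terminal oxidase genes 17 rose and none fell, also when adjusted over the list alone (camera adjusted p = 4.02e-06, and adjusted p = 0.375 with an estimated correlation), with subunits II and I of a cytochrome c oxidase (A391DRAFT_2340 and A391DRAFT_2341) up by 6.08 ± 0.11 and 5.75 ± 0.12. All 9 ATP synthase genes rose, also when adjusted over the list alone (camera adjusted p = 0.000298, and adjusted p = 0.375 with an estimated correlation). Of 16 complex I genes 13 rose and 1 fell, with 14 and 1 adjusted over the list alone (camera adjusted p = 0.00368, and adjusted p = 0.375 with an estimated correlation). Of 58 ribosomal protein genes 50 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 9.38e-10, and adjusted p = 0.375 with an estimated correlation). One S4 copy (A391DRAFT_0461), which lies within the hemin uptake block, rose by 5.99 ± 0.10 and L2 (A391DRAFT_2547) by 2.19 ± 0.09.

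Formaldehyde assimilation followed. In the ribulose monophosphate cycle list 7 of 8 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.00944, and adjusted p = 0.375 with an estimated correlation). Hexulose-6-phosphate synthase A391DRAFT_1263 rose by 2.27 ± 0.13, its second copy A391DRAFT_2587 by 0.63 ± 0.12 and 6-phosphogluconate dehydrogenase (A391DRAFT_0070) by 2.60 ± 0.10. In the tetrahydromethanopterin list 3 of 9 rose and 3 fell, also when adjusted over the list alone. Formaldehyde activating enzyme (A391DRAFT_1348) rose by 1.15 ± 0.10 and formylmethanofuran dehydrogenase subunit B (A391DRAFT_1921) fell by 0.73 ± 0.10. Superoxide dismutase (A391DRAFT_0376) rose by 3.03 ± 0.11 and a peroxiredoxin (A391DRAFT_1307) by 2.81 ± 0.14, although 12 of 27 oxidative stress genes fell and 4 rose, also when adjusted over the list alone.

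Most nitrogen assimilation genes fell. A nitrate transporter permease (A391DRAFT_1009) fell from 14360 ± 580 to 158.8 ± 8.18 counts (log2 -6.49 ± 0.09, adjusted p = 1.68e-07), the nitrite reductase using NAD(P)H (A391DRAFT_1012) fell by 6.19 ± 0.12 on the log2 scale and the nitrogen regulator P-II (A391DRAFT_0878) fell by 5.36 ± 0.09. Of 18 nitrogen assimilation genes 13 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.00884, and adjusted p = 0.375 with an estimated correlation). Beside P-II, a metal efflux pump and its partner genes (A391DRAFT_0879, A391DRAFT_0880 and A391DRAFT_0881) had log2 changes of -5.92 ± 0.09, -7.54 ± 0.13 and -7.84 ± 0.17. An ANTAR-domain response regulator (A391DRAFT_1007) fell by 7.95 ± 0.29. The largest fall by the naming rule was that of a PDZ-domain serine protease (A391DRAFT_0982), which fell by 9.22 ± 0.12 on the log2 scale, from 143300 ± 5955 to 240.7 ± 36.5 counts. A chemotaxis signal protein (A391DRAFT_1946) and a methyl-accepting chemotaxis protein (A391DRAFT_1956) fell, with log2 changes of -7.41 ± 0.16 and -7.42 ± 0.16, while 36 of 67 flagellar and chemotaxis genes rose and 16 fell, also when adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.375 with an estimated correlation).

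In the pilus and secretion list of strain 13, 24 of 43 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.0326, and adjusted p = 0.375 with an estimated correlation), and an abundant prepilin-type gene (A391DRAFT_2281) fell by 2.26 ± 0.13. In the metal efflux and copper list 14 of 25 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.375 with an estimated correlation). In the amino acid synthesis list 21 of 42 rose and 8 fell, also when adjusted over the list alone, without a camera call (adjusted p = 0.0778), and ketol-acid reductoisomerase (A391DRAFT_2276) rose by 1.99 ± 0.09. Of 29 mobile element genes 12 fell and 1 rose, with 11 and 0 adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.375 with an estimated correlation). Limma called 1764 of 2579 genes, 906 higher and 858 lower, and 756 changed at least 2-fold. Leaving out single libraries gave 1283 to 1921 genes.

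**Figure D3:**
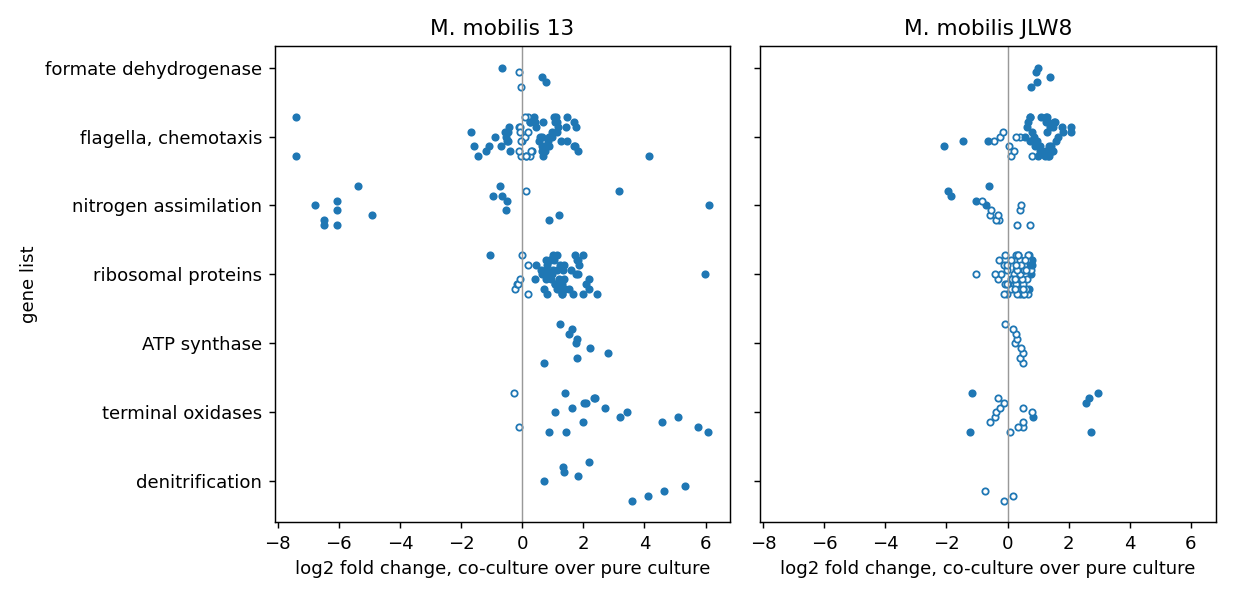
Log2 fold changes, co-culture over pure culture, of the genes in 7 lists for M. mobilis 13 (left) and M. mobilis JLW8 (right), with a point per gene, filled where the limma adjusted p was under 0.05. All 9 denitrification genes of strain 13 lie right of 0, while the 3 of strain JLW8 are open points on both sides of it.

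In M. mobilis JLW8 a dehydrogenase of the methanol dehydrogenase family and genes of an oxidase rose. The PQQ-dependent dehydrogenase Mmol_2048 rose from 58200 ± 3504 to 721500 ± 62400 normalized counts (mean ± SD, n = 2 per group), a log2 change of 3.63 ± 0.48 (limma adjusted p = 2.77e-11, and 0.0227 with voom). It took 0.739% and 0.797% of JLW8 reads in pure culture and 6.80% and 7.04% in the mixture. Subunits I and II of a cytochrome c oxidase (Mmol_0553 and Mmol_0554) rose by 2.95 ± 0.35 and 2.74 ± 0.33, with adjusted p = 0.0245 for both with voom. The assembly protein Mmol_0552 beside them rose by 2.66 ± 0.23 and the oxidase gene Mmol_0551 by 2.57 ± 0.30 (adjusted p = 0.0227 and 0.0317 with voom). Of 19 terminal oxidase genes 5 rose and 2 fell, also when adjusted over the list alone, and 4 rose with voom. Under scaling by total reads 4 were higher and 7 lower, and the list's median log2 change turned from 0.33 to -0.13.

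By the naming rule, the steepest falls were in enzymes that work without vitamin B12, for which no list was tested. The alpha subunit of ribonucleoside-diphosphate reductase (Mmol_1920), which makes DNA precursors, fell from 35990 ± 8171 to 644.1 ± 171.7 counts (log2 -5.81 ± 0.26, limma adjusted p = 1.75e-71, and 0.0144 with voom), and its neighbour Mmol_1921 fell by 5.36 ± 0.22 on the log2 scale (adjusted p = 0.024 with voom). The B12-independent methionine synthase (Mmol_0966) fell by 5.25 ± 0.29 (adjusted p = 0.0254 with voom). A TonB-dependent receptor (Mmol_0280) fell by 3.48 ± 0.23 (adjusted p = 0.0242 with voom) and a second one (Mmol_0537) fell by 1.84 ± 0.22 (adjusted p = 0.0376 with voom). In the iron transport list 11 of 31 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0367, and adjusted p = 0.558 with an estimated correlation), and 2 fell and 1 rose with voom. Under scaling by total reads 13 were lower and 1 higher.

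Motility genes of JLW8 rose as a group. In the flagellar and chemotaxis list 38 of 50 rose and 3 fell, with 39 and 3 adjusted over the list alone (camera adjusted p = 3.46e-13, and adjusted p = 0.558 with an estimated correlation), and 10 rose with voom, while under scaling by total reads 24 were higher and 3 lower. The flagellar gene Mmol_0920 rose by 1.79 ± 0.25, with adjusted p = 0.0747 with voom. All 5 formate dehydrogenase genes rose, also when adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.558 with an estimated correlation), none of them with voom and 1 under scaling by total reads, and the gamma subunit Mmol_2035 rose by 1.01 ± 0.22 (adjusted p = 0.0657 with voom and 0.0843 under scaling by total reads). In the PQQ list 5 of 10 rose and 6 adjusted over the list alone (camera adjusted p = 0.0406, and adjusted p = 0.558 with an estimated correlation), 1 of them with voom, the gene for biosynthesis protein A (Mmol_0459, log2 2.20 ± 0.35, adjusted p = 0.0375 with voom and 0.0559 without co-culture replicate 1). Under scaling by total reads 2 genes of the PQQ list were higher and 1 lower. Of 61 ribosomal protein genes 5 rose, 0 adjusted over the list alone (camera adjusted p = 0.00693, and adjusted p = 0.8 with an estimated correlation of 0.71). That list's median log2 change of 0.35 became -0.11 under scaling by total reads, with 4 lower and 0 higher, which moved the median of all JLW8 genes to -0.44.

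Nitrate transport genes of JLW8 passed with limma on the deposited values and not with voom. Of 15 nitrogen assimilation genes 5 fell, and 6 adjusted over the list alone (camera adjusted p = 0.0406, and adjusted p = 0.558 with an estimated correlation), none with voom and 10 under scaling by total reads. The nitrate transporter genes Mmol_1656 and Mmol_1655 had log2 changes of -1.94 ± 0.33 and -1.84 ± 0.39 (adjusted p = 0.178 and 0.273 with voom). All 8 mobile element genes had lower means and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.669 with an estimated correlation), none with voom. An integrase gene (Mmol_0072) had 991 and 2317 counts in pure culture and 199.3 and 297.4 in the mixture (adjusted p = 0.249 with voom). These low genes stood beside a difference between libraries: 1% of JLW8 genes lay below 152 and 231 counts in the pure cultures and below 65.1 and 81.4 in the mixture, while for strain 13 the same values were 7.81 and 8.65 against 9.21 and 14.8.

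The denitrification genes of JLW8 did not pass with limma on the deposited values. In the denitrification list 1 of 3 members had a positive log2 change, and the median was -0.11. Under scaling by total reads 1 member was lower, with a median of -0.57. Copper nitrite reductase (Mmol_1061) had 12570 ± 1905 counts in the mixture and 10640 ± 2170 in pure culture (log2 0.25 ± 0.33, adjusted p = 0.623, and 0.631 with voom), and nitric oxide reductase (Mmol_1051) a log2 change of 0.17 ± 0.36 (adjusted p = 0.763, and 0.812 with voom). Both changes turned negative under scaling by total reads. The hexulose-6-phosphate synthase genes Mmol_0313 and Mmol_1338 had log2 changes of 0.81 ± 0.43 and 0.70 ± 0.46 without passing (adjusted p = 0.16 and 0.268, and 0.295 and 0.363 with voom), and passed without pure-culture replicate 1 (adjusted p = 0.0343 and 0.0432). The assimilatory nitrate reductase Mmol_1648 had one of -0.57 ± 0.26 (adjusted p = 0.0875, and 0.299 with voom), and passed under scaling by total reads (adjusted p = 0.000188). A second methanol dehydrogenase family gene (Mmol_1770) fell by 2.16 ± 0.30 on the log2 scale, with adjusted p = 0.206 with voom. Limma called 614 of 2338 genes, 254 higher and 360 lower, 373 of them at least 2-fold, whereas voom called 56, 45 higher and 11 lower. Leaving out pure-culture replicate 2 gave 286 genes, and leaving out co-culture replicate 1 or 2 gave 302 and 228. Scaling by total reads gave 13% higher in place of 41.4%.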

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

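Of the tests below, the ratio of chaperone reads to strain 13 reads was chosen before its result was seen, and the other 5 were chosen after. The genes listed differ between the partners of M. tundripaludum in a test of that difference, the limma contrast of both co-cultures.

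This contrast called 513 genes. Of the 40 named in this part, 13 lost the call under at least 1 alternative: T449DRAFT_3653, T449DRAFT_2064, T449DRAFT_2409, T449DRAFT_4567, T449DRAFT_0926, T449DRAFT_0925, T449DRAFT_4368, T449DRAFT_3739, T449DRAFT_1782, T449DRAFT_1883, T449DRAFT_2147, T449DRAFT_2559 and T449DRAFT_0908. T449DRAFT_3653 lost it under scaling by total reads (adjusted p = 0.102), in a fit of these groups alone (adjusted p = 0.0767) and without JLW8 replicate 1 or 2 or strain 13 replicate 1 (adjusted p = 0.119, 0.135 and 0.0882). Higher with JLW8 were T449DRAFT_3653 (hemerythrin-like, log2 2.08), T449DRAFT_3237 (ferrienterochelin receptor, 1.74), T449DRAFT_4400 (chemotaxis receptor, 1.52), T449DRAFT_2451 (hydroxylamine reductase, 1.33), T449DRAFT_2028 (delta-aminolevulinic acid dehydratase, 1.31), T449DRAFT_2030 (an oxidoreductase, 1.26), T449DRAFT_4398 (chemotaxis signal protein, 1.05), T449DRAFT_0568 (phage lysozyme, 0.97) and T449DRAFT_0442 (CRISPR protein, 0.83). By smaller steps T449DRAFT_4417 (cytochrome d oxidase, 0.74), T449DRAFT_4529 (a cyclohydrolase of formaldehyde oxidation, 0.63), T449DRAFT_1883 and T449DRAFT_2147 (ribosomal proteins, 0.53 and 0.47) and T449DRAFT_1782 (FdhD of formate dehydrogenase, 0.49) were higher too.

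Lower with JLW8 were the folding genes T449DRAFT_2064 (log2 -3.07), T449DRAFT_2409 (-2.59), T449DRAFT_4567 (-2.43), T449DRAFT_0926 (-2.37), T449DRAFT_0925 (-2.14) and T449DRAFT_4140 (-1.17), and the efflux genes T449DRAFT_2562 (-2.33), T449DRAFT_2563 (-2.32), T449DRAFT_2503 (-1.04) and T449DRAFT_1153 (-0.82). So were truncated hemoglobin T449DRAFT_2569 (-1.45), glutaredoxin T449DRAFT_4368 (-1.18), superoxide dismutase T449DRAFT_1764 (-1.04), and the exopolysaccharide genes T449DRAFT_3274 (-1.30) and T449DRAFT_3275 (-1.09). The pilus genes T449DRAFT_0646 (-1.14) and T449DRAFT_0647 (-1), the complex I genes T449DRAFT_2522 (-1.26) and T449DRAFT_2525 (-0.88) and the oxidase subunit T449DRAFT_3742 (-0.91) were lower. The remaining lower genes were T449DRAFT_3555 (isopropylmalate synthase, -1.07), T449DRAFT_3268 (a hydrogenase subunit, -0.83), T449DRAFT_1802 (flagellar chaperone, -0.82), T449DRAFT_3739 (formaldehyde activating enzyme, -0.64), T449DRAFT_2559 (homoserine kinase, -0.41) and T449DRAFT_0908 (GreA, -0.39).

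The chaperone genes of M. tundripaludum were higher with strain 13. Strain 13 reads counted on these genes are argued against as the source. The called genes gained 21.9 and 20.1 times the reads of the whole strain 13 chaperone list in the same libraries. Reads placed on the wrong strain could be missing from that list, so they are not excluded. A single co-culture library is argued against as the source of the list's call, which had a camera adjusted p of 1.24e-07 without replicate 1, although it had 0.487 with an estimated correlation. Single genes such as ClpB (T449DRAFT_2064) lost their calls without either pure-culture library, with log2 changes of 2.52 and 2.86 against 2.69 with all libraries. A response to the partner, which the design names, stays open and was not tested.

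The calcium-type methanol dehydrogenase gene T449DRAFT_4155 was higher with JLW8 without passing over all genes in the fit of all groups (adjusted p = 0.081), and passed in a fit of the 2 groups (adjusted p = 0.000429) and without robust moderation (adjusted p = 0.0155). JLW8 reads are argued against as the source: the gene gained 5.83 and 2.77 times the reads of all such large subunit genes of JLW8. Reads placed on the wrong strain could be missing from that total, so they are not excluded. The scaling between libraries is argued against as well, since the log2 ratio to T449DRAFT_3928 within each library lay at least 5.19 higher in the co-cultures than in the pure cultures. With strain 13 the ratio of gained reads was 0.671 and 0.365, which does not argue against reads of strain 13 as the source there. A change in lanthanum supply could not be tested, as the labels do not say which libraries had it.

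With JLW8 genes ranked by mean level into 3 equal classes, 93.5% of the called genes in the weakest class were lower in co-culture against 18% in the strongest, a difference of 75.5 points, while for strain 13 the shares were 48.6% and 49%. These shares restate the pattern, so they do not test whether background reads spread over all genes in the JLW8 pure cultures are its source. The pure cultures differed from each other along the same classes, with a median log2 of replicate 2 over replicate 1 of 0.47 in the weakest and -0.25 in the strongest, against -0.48 and 0.34 for co-culture over pure culture. Lower depth in co-culture is argued against, since 92.9% were still lower after thinning to equal totals. Per the labels the RNA was checked for DNA by PCR, and background reads, another difference between libraries and a lower expression of weakly expressed genes with the partner stay open.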

How the results depend on the processing

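Scaling by total reads, both other pseudocounts, voom, fits without robust moderation, the higher minimum mean and the split of the pure-culture libraries between comparisons were chosen after the data were seen, and the other alternatives before. The counts of changed genes stayed within 1.5 times under trimmed mean scaling, both other pseudocounts, no low-value filter and thinning. Whether equal replicate numbers pair samples is open: the labels do not say, and the deviations of same-numbered libraries had correlations of -0.2, -0.41 and 0.21 for M. tundripaludum, 0.08 for strain 13 and 0.05 for JLW8. A replicate block gave 108 genes for M. tundripaludum with strain 13, 9 with JLW8, 337 between partners and 4 shared. A 2-fold minimum gave 57, 11 and 106 for these comparisons, 756 for strain 13 and 373 for JLW8, fewer by construction. For JLW8, voom gave 56 genes and a minimum mean of 1000 counts gave 289, while between partners a fit of 2 groups gave 301. With an estimated correlation 0 lists were called in each of the 5 comparisons. Thinning left 5 called lists in place of 9 for the genes of JLW8. Scaling by total reads gave 10 called lists in place of 6 for M. tundripaludum with strain 13. Without the 10 most abundant features the JLW8 share was 13.231%. Where no construction is named, the cause was not tested.

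Leaving out single libraries, where a lone library is assumed to vary like the other groups, gave 48 to 317 genes with strain 13, 7 to 295 with JLW8, 223 to 603 between partners and 228 to 829 for JLW8. Shared genes ranged from 2 to 25, and called lists from 5 to 10 with JLW8 and from 6 to 9 between partners. Among named genes 720 values kept direction and side of the threshold when a library was left out, 129 lost a call, 6 gained one and 13 reversed. In the lost calls the log2 change was 0.421 to 1.26 times that with all libraries, with a median of 0.955, and in 46 it was at least as large. Reversed genes, none called in the comparison, ranged with strain 13 from -0.123 to 0.176 (T449DRAFT_4629). With JLW8 they ranged from -0.126 to 0.066 (T449DRAFT_2846), -0.029 to 0.194 (T449DRAFT_2847), -0.032 to 0.264 (T449DRAFT_2848) and -0.057 to 0.229 (T449DRAFT_1928). Between partners they ranged from -0.062 to 0.237 (T449DRAFT_4629) and -0.043 to 0.228 (T449DRAFT_1929), and in JLW8 from -0.289 to 0.637 (Mmol_1051). Scaling by total reads turned T449DRAFT_2847 (-0.027) and T449DRAFT_1928 (-0.024) with JLW8, T449DRAFT_4629 (-0.087), T449DRAFT_1929 (-0.083) and T449DRAFT_3186 (-0.036) between partners, and Mmol_1061 (-0.211) and Mmol_1051 (-0.285). The planned count tests and the removal of ribosomal RNA were not run, as the tables hold normalized values and no such genes.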

Other observations

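All values here were looked at after the results were seen, and so were both tests. Genes with neighbouring locus tags moved together in M. tundripaludum with M. mobilis 13. Besides the siderophore synthetase, T449DRAFT_3948 (lysine/ornithine N-monooxygenase) rose by 2.78 ± 0.19, T449DRAFT_3947 (an efflux permease) by 2.69 ± 0.20 and T449DRAFT_3949 (a glutamate decarboxylase-like enzyme) by 1.55 ± 0.19 on the log2 scale. The flavodoxin reductase gene T449DRAFT_2450, next to hydroxylamine reductase, rose by 2.47 ± 0.12 with strain 13 (limma adjusted p = 3.02e-05). The gene for the signal molecule synthase of quorum sensing (T449DRAFT_2014) fell by 0.71 ± 0.12 with strain 13 (adjusted p = 0.0121) and was higher with JLW8 than with strain 13 by 1.15 ± 0.12 (adjusted p = 0.000588).

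Methane monooxygenase subunits C, A and B took 33.1% and 35.2% of M. tundripaludum reads in pure culture, 24.2% and 30.6% with strain 13 and 34% and 32.4% with JLW8. Among 415 pairs of genes with the same product text in both M. mobilis strains, 22 were called higher in both, 7 lower in both and 15 in opposite directions. The log2 changes had Pearson's r = 0.2 and Spearman's rho = 0.09 across these genes, which are not independent replicates.

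A hypothesis was that M. mobilis gained cobalamin in co-culture, as JLW8 genes of B12-independent enzymes fell. The values for strain 13 go both ways: its B12-independent methionine synthase (A391DRAFT_1407) rose by 2.50 ± 0.20, while its ribonucleoside-diphosphate reductase genes A391DRAFT_1408 and A391DRAFT_1409 had log2 changes of -1.64 ± 0.20 and -1.04 ± 0.26. In JLW8 the list of cobalamin and vitamin genes was lower without passing (camera adjusted p = 0.103). Of its 8 members 2 fell, also when adjusted over the list alone, 0 with voom and 4 under scaling by total reads. The B12-dependent methionine synthase Mmol_2286 and reductase Mmol_0049 had log2 changes of -0.03 ± 0.31 and -0.75 ± 0.39, and neither passed. The hypothesis may hold for JLW8, and these values do not decide it.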
